A study of Mus musculus with 6 samples.

How the data were processed

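Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in epithelial cells of the adult mouse intestine. About 50K cells were purified by flow cytometry for each of 6 libraries, and paired-end reads were taken on a HiSeq instrument, per the labels' protocols. The 6 libraries formed 3 groups of 2: wild-type ileum, wild-type colon and colon in which Satb2 had been deleted with an inducible Cre recombinase driven by the villin promoter. Wild-type animals carried the floxed Satb2 alleles without the recombinase, per the labels.

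The deposited files were 6 lists of peak summits, 1 per library. Peaks were called with MACS2 on the mm10 genome, and R 3.6.0 and ChIPseeker are also named, per the submitters' processing notes. The MACS2 version, the aligner, duplicate removal, any read shift and the calling threshold are not given in the sources used here. Each line of these lists held a chromosome, a position column marking a summit of 1 bp, a name belonging to a single sample, and the peak caller's score. The authors had thus called peaks per sample, and these lists held no peak widths. The deposited score was a −log10 significance: its smallest value lay just above 2 in every list, as a p-value or q-value limit of 0.01 would give, and the labels do not say which of these it was. Read counts were not used here, and the sequencing depth behind the lists was unknown. The number of summits per library, 66429 to 74077, is the nearest measure of yield. Because a score grows with depth, scores were used only to rank summits within their own list, and no test compared them between lists. The highest scores were 5181 and 4995 in wild-type colon against 8773 to 15590 in the other lists. Median scores were 27.6 and 25.7 in wild-type colon, 32.8 and 27.5 in knockout colon and 38.3 and 45.0 in ileum. Depth or quality may thus differ between wild-type colon and the other groups, which was not tested.

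Summits of all 6 libraries on chromosomes 1 to 19, X and Y were joined into regions wherever neighbouring summits lay at most 250 bp apart. A region was counted as found in a library that had at least 1 summit in it. A region was called ileum-only when it was found in both wild-type ileum libraries and in neither wild-type colon library, and colon-only in the opposite case. It was called gained when found in both knockout colon libraries and in neither wild-type colon library, and lost in the opposite case. The same counts were made for the 2 other ways of splitting each set of 4 libraries, as the level that replicate differences give. A region missing from a list is one without a called summit, which is not proof of closed chromatin.

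Genes came from the RefSeq table of GRCm38.p6, the assembly behind mm10. That table gives gene bodies without their strand, so the planned assignment to the nearest transcription start was replaced by assignment to the nearest protein-coding gene body within 100 kb, after the files had been seen. A region inside a gene had a distance of 0, and the share of regions within 1 kb of either gene end took the place of a promoter share. A genome sequence was not used here, and the planned search for 22 transcription factor motifs was not run.

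The test planned for genes was limma on log2 of the number of regions per library plus a pseudocount of 1. In simulated data for knockout against wild-type colon, with 10976 genes of which 200 were changed by known amounts, 80.3% of the 289 genes it called were unchanged ones. In the real data 43.4% of its calls between ileum and colon, and 53.5% of those between knockout and wild-type colon, came from genes whose replicates had equal numbers in all 3 groups, which leaves no spread to measure. A version of limma with the spread pooled over genes was then tried on simulated data and also set aside. The test used in its place, chosen after limma had failed on simulated data and after its calls on the real data had been counted, was a two-sided exact permutation test per gene. It permuted the library labels within each region of the gene among the 4 libraries compared and summed over the regions. Genes with at least 3 regions were tested, 10976 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. On the simulated data it called 0 of 10776 unchanged genes. It recovered 8.00% of 50 genes that opened 50% of their closed regions and 32.0% of those that opened 90%. It recovered 20.0% of 50 genes that closed 50% of their regions and 56.0% of those that closed 75%. The test treats the regions of a gene as independent of each other, and the simulation drew them independently in every library. The simulated calls therefore cannot show its error rate where neighbouring regions open together. The p-values of the test take regions as the units and describe these libraries. Nothing in the labels says that the replicates came from separate animals. Neither the gene p-values nor the list p-values, which rest on random gene lists, measure the spread between libraries or animals.

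Gene lists were tested by the mean per gene of ileum-only minus colon-only regions, or of gained minus lost regions. The reference was 100000 random lists of the same size, matched in 10 bins of the number of regions per gene, and the permutation test was two-sided. Its smallest possible p was 2e-05. Of 322 listed genes 321 were found in the annotation, the exception being Pla2g2a. The 22 lists covered lipid absorption, bile acid handling, brush-border digestion and nutrient transport, xenobiotic and retinoid metabolism, Paneth cells, colonic ion and water transport, colonocyte identity, goblet cells, posterior Hox genes, intestinal transcription factors, stem cells and Wnt signalling, the cell cycle, enteroendocrine cells, tuft cells, MHC class II and housekeeping genes. They also held markers of T cells, B and plasma cells, myeloid cells, stroma and smooth muscle, endothelium, and enteric neurons and glia. P-values were adjusted over the 22 lists of a comparison. On simulated data for knockout against wild-type colon over 17061 genes, 0 of 200 lists of unchanged genes had an unadjusted p under 0.05, and all 20 lists with planted changes did. The lists of unchanged genes were set against random lists that could hold changed genes, and each simulated region was drawn independently. These counts therefore do not give the error rate on the real lists.

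The share of ileum-only regions found in knockout colon was set against a colon library that had no part in defining them. For this, regions were defined on both ileum libraries and 1 wild-type colon library, and the other wild-type colon library was held out, in both possible ways. The difference was tested with an exact permutation test of 2 against 2 libraries, whose smallest p is 0.333. Because both comparisons use the same wild-type colon libraries, 100 simulated unchanged groups were set against those libraries for regions and 20 for genes.

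The genes named in the text were Satb2, the 8 genes with the largest rise and the 8 with the largest fall in mean region number among those called in each comparison, and up to 4 members of each list by the size of their net region number. Single regions were the distal ones of those genes with the highest score rank. The rule, the lists, the joining distance, the region definitions and most of the other settings tried were fixed before the data were examined. The rule was written for limma's calls and applied to those of the exact test. A gene named from outside it is said to be so chosen.

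Alternatives tried were joining distances of 100 and 500 bp, lists of equal length, the top 33214 summits of each list, a stricter limit, autosomes alone, distances to genes of 25 kb or of 10 kb, minimums of 1 and 6 regions per gene, a pseudocount of 0.5, limma in place of the exact test, Fisher's exact test per gene, a replicate block and leaving out each library in turn. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.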

Results

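Open chromatin was mapped by ATAC-seq in sorted intestinal epithelium of adult mice, in 2 libraries each of wild-type ileum, wild-type colon and Satb2 knockout colon. Satb2 encodes a chromatin-binding transcription factor of the colonic epithelium. The comparison of ileum with colon asks which regions distinguish the small and large intestine, and that of knockout with wild-type colon asks what the loss of Satb2 does to the colon. The lists held 71615 and 70323 summits for wild-type ileum, 74077 and 68700 for wild-type colon, and 71029 and 66429 for knockout colon. Joined, they gave 121664 regions, of which 35186 (28.9%) were found in all 6 libraries and 28887 (23.7%) in 1 alone. Of all regions, 92.0% lay within 100 kb of a protein-coding gene and 54.6% inside one.

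The targeted gene, Satb2 (mm10 chromosome 1, 56793981 to 56981190), had 25 and 22 regions in the wild-type colon libraries, 23 and 28 in knockout colon and 9 and 14 in ileum. Its region number was lower in ileum than in wild-type colon by the exact permutation test (adjusted p 0.000501, 2 libraries per group), and knockout and wild-type colon did not differ by it (exact adjusted p 1.00). Between knockout and wild-type colon, 4 of its regions were gained and 7 were lost. The sources used here do not say which part of Satb2 was deleted, so its summits do not check the knockout labels. The ileum call ended without ileum replicate 1 or wild-type colon replicate 1 (highest exact adjusted p 0.0854).

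Knockout colon lay between the wild-type tissues in the regions it shared. Wild-type colon libraries had 43.4% to 49.8% of their joint regions in common with ileum libraries. Knockout libraries shared 62.6% and 62.9% with ileum replicate 1, 54.9% and 55.2% with ileum replicate 2, and 54.4% to 55.0% with wild-type colon. Replicates shared 77.7% in wild-type colon, 78.7% in knockout colon and 60.9% in ileum. Ileum replicate 2 held 9758 regions found in no other library, against 1745 to 5803 in the others.

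**Figure D1:**
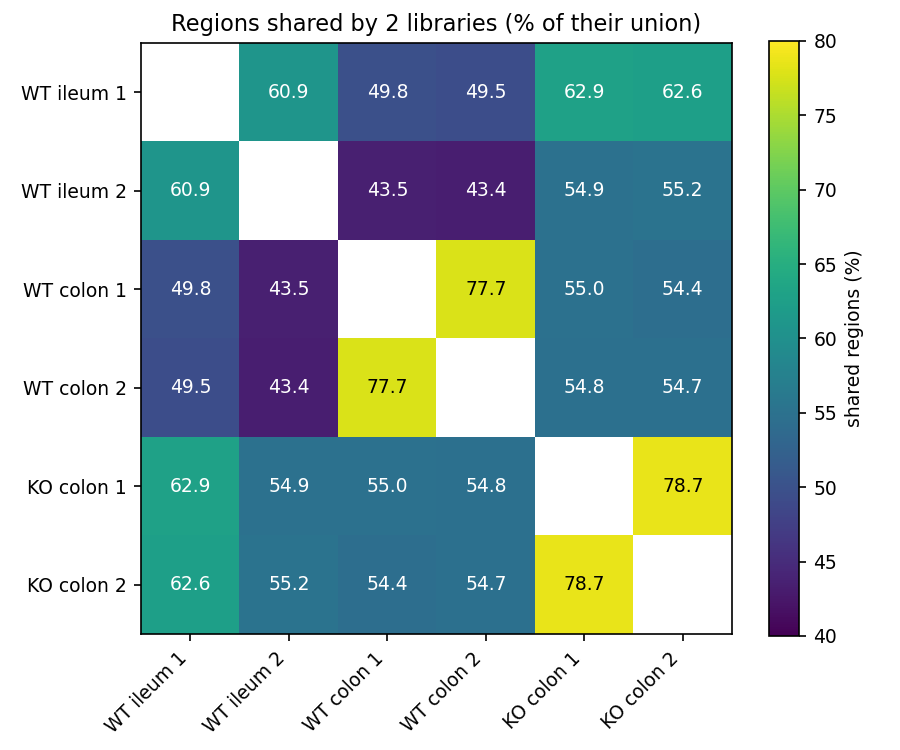
Percent of the joint regions of each pair of libraries that both libraries hold, for the 6 libraries of wild-type ileum, wild-type colon and Satb2 knockout colon. Replicates of colon share 77.7% and 78.7%, and knockout colon shares 54.4% to 62.9% with the other groups.

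Wild-type ileum carried more open regions than wild-type colon at genes of small-intestinal digestion and absorption. At Mme, which encodes the brush-border peptidase neprilysin (chromosome 3, 63295211 to 63383713), the mean was 14.5 ± 0.707 regions in ileum against 1 in each colon library (SD, n = 2; exact adjusted p 1.8e-07). The colonic carbonic anhydrase gene Car1 had none in either ileum library against 12.5 ± 2.12 in colon (SD, n = 2; exact adjusted p 1.03e-06). The sodium-calcium exchanger gene Slc8a1 had 2 and 1 regions in ileum against 24 and 21 in colon (exact adjusted p 2.25e-12). In all, 12467 regions were ileum-only and 15132 colon-only, 27599 together, while the 2 other splits of these libraries gave 1978 and 1721. Resting on 1 ileum library, the ileum-only regions numbered 24785 without replicate 1 and 21136 without replicate 2. Of the ileum-only regions 5.08%, and of the colon-only regions 5.28%, lay within 1 kb of a gene end, against 28.9% of the regions found in all 6 libraries.

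By the exact permutation test, 241 genes had more regions in ileum and 309 had fewer, of 10976 tested. Among the largest rises were Adcy8, an adenylate cyclase gene, with 14 and 17 regions in ileum against 4 and 2 in colon (exact adjusted p 3.29e-05), and Fbxl17, with 18 and 20 against 8 and 6 (0.000364). Pde4d, Zmiz1, Fhit, Prkce and Eepd1 completed that group of 8 with Mme, at exact adjusted p from 0.00216 to 0.0435. Among the largest falls, the zinc-finger gene Glis3 had 5 and 7 regions in ileum against 31 and 31 in colon (exact adjusted p 2.75e-11). Cdkal1 had 11 and 8 against 31 and 31 (1.06e-08, exact), and the receptor phosphatase gene Ptprt 20 and 17 against 38 and 38 (1.19e-07, exact). Mcc, Mecom, Auts2 and Magi1 completed that group with Slc8a1, at exact adjusted p from 2.19e-07 to 0.00018. High-ranking ileum-only regions lay inside Mme (chromosome 3, 63359649 to 63359708) and 20449 bp outside Eepd1 (chromosome 9, 25461044 to 25461084). High-ranking colon-only ones lay 4887 bp outside Slc8a1 (chromosome 17, 81743259 to 81743290) and inside Mecom (chromosome 3, 30011000 to 30011034).

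The brush-border digestion and transport list had 79 ileum-only and 17 colon-only regions over its 25 genes, a net of 2.48 per gene against −0.269 in random lists. Its permutation p was 2e-05, the smallest possible, and 0.00044 adjusted, with 17 members leaning to ileum, 2 to colon and 6 at a net of 0. Of its 24 tested members 10 were called with more regions and none with fewer, also 10 when adjusted over the list alone. They included the sodium-glucose transporter gene Slc5a1 (22 and 20 against 11 and 8), the peptide transporter gene Slc15a1 (21 and 20 against 12 and 10) and the proline transporter gene Slc6a20a (8 and 8 against 1 and 1). The lipid absorption list had 34 ileum-only and 13 colon-only regions, a net of 1.05 per gene (permutation adjusted p 0.0405), with 11 members leaning to ileum, 2 to colon and 7 at 0. Mttp, needed for chylomicron assembly (8 and 7 against 1 and 2), Npc1l1, which takes up cholesterol (7 and 7 against 1 and 2), and Acsl5 (6 and 6 against 2 and 2) were called with more. Adjusted over the list alone, 5 were called with more regions and 1 with fewer. The lipid list missed the threshold without ileum replicate 1 (0.118, permutation), wild-type colon replicate 1 (0.0893) or knockout colon replicate 2 (0.0508).

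Colonic ion and water transport leaned to colon without passing, with 17 ileum-only against 57 colon-only regions, a net of −2 per gene (permutation adjusted p 0.0603). Among its members Car1 and the sodium channel gene Scnn1b (none against 5 and 6) were called with fewer regions in ileum, 4 in all, or 6 adjusted over the list alone. The colonocyte list had 2 against 23 regions (adjusted p 0.0757, permutation), with the glycosyltransferase gene B3galt5 (5 and 11 against 19 and 19) and the transglutaminase gene Tgm3 (2 and 3 against 9 and 8) called with fewer, 3 over the list alone. Posterior Hox genes had 2 against 15 (adjusted p 0.0757, permutation) and none was called, 2 when adjusted over the list alone. Hoxa11 was found at 3 regions in each colon library and at none in ileum. Of single genes in other lists, the ileal bile acid carrier gene Fabp6 had 10 and 9 regions in ileum against 3 and 3, the drug-metabolising Cyp3a25 9 and 8 against 2 and 1, and the stem cell gene Olfm4 11 and 6 against 1 and 2, all called with more. The transcription factor genes Gata4 (12 and 14 against 6 and 7) and Maf (14 and 16 against 5 and 5) were called with more, and the crypt receptor genes Ephb3 (12 and 7 against 18 and 18) and Lrig1 (23 and 18 against 30 and 32) and the tuft cell gene Hpgds (2 and 1 against 6 and 5) with fewer. Exact adjusted p for these 8 genes ran from 0.000216 to 0.0477. Fabp6 was the only gene called of the 9 in the bile acid list. There the ileal bile acid transporter gene Slc10a2 had 15 and 17 regions in ileum against 16 and 16 in colon.

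The other 17 lists did not pass, at permutation adjusted p from 0.273 to 0.983. Ileum-only against colon-only regions were 19 and 9 for bile acid handling, 26 and 15 for xenobiotic metabolism, 4 and 7 for Paneth cells, 20 and 29 for goblet cells, and 52 and 58 for intestinal transcription factors. They were 27 and 56 for stem cells and Wnt, 4 and 5 for the cell cycle, 11 and 10 for enteroendocrine cells, 7 and 17 for tuft cells, 2 and 2 for MHC class II, and 10 and 4 for housekeeping genes. Markers of other cell types had few: 2 and 3 for T cells, 0 and 1 for B cells, 1 and 3 for myeloid cells, 6 and 3 for stroma, 3 and 8 for endothelium, and 1 and 6 for neurons and glia. Of 45 named gene calls 17 were kept whichever of the 4 libraries was left out, among them Mme, Slc6a20a, Car1, Slc8a1, Glis3 and Cdkal1. The calls for Mttp, Npc1l1, Acsl5, Scnn1b, Tgm3, Gata4, Hpgds and Neto1 ended in each omission, with exact adjusted p up to 0.396, and the genes called numbered 122 without colon replicate 1, 125 without colon replicate 2, 129 without ileum replicate 2 and 323 without ileum replicate 1.

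Knockout colon had more regions than wild-type colon at brush-border genes, and fewer at the colonic genes Car1, Tgm3 and B3galt5. Mme had a mean of 16.5 ± 0.707 regions in knockout against 1 in each wild-type colon library (SD, n = 2; exact adjusted p 4.67e-09). The sucrase-isomaltase gene Sis (chromosome 3, 72888557 to 72967863) had 22 and 17 against 6 and 5 (exact adjusted p 8.18e-06). Car1 fell to 1 region in each knockout library, from 11 and 14 (exact adjusted p 4.86e-06). In all, 11762 regions were gained and 13345 lost, 25107 together, while the other splits of these 4 libraries gave 1414 and 1120. Without wild-type colon replicate 2 the lost regions numbered 20388. Of the gained regions 4.97%, and of the lost 5.80%, lay within 1 kb of a gene end.

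By the exact permutation test, 126 genes had more regions in knockout colon and 245 had fewer, of 10976. The largest rise was at Hcn1, a pacemaker channel gene (chromosome 13, 117602320 to 117981028), with 33 and 28 regions against 2 and 2 (exact adjusted p 4.02e-18). The latrophilin gene Adgrl3 had 36 and 37 against 9 and 8 (1.35e-13, exact), the kainate receptor gene Grik1 22 and 19 against 7 and 6 (6.34e-06, exact), and Neto1, an auxiliary subunit of such receptors, 12 and 12 against 1 and 1 (5.91e-06, exact). Rabgap1l (33 and 35 against 15 and 14) and the proprotein convertase gene Pcsk6 (16 and 15 against 4 and 3) also rose. Ptprt had the largest fall, to 10 and 10 from 38 and 38 (exact adjusted p 1.03e-14). Lrmda fell to 9 and 8 from 28 and 31 (2.5e-10, exact), Ldlrad3 to 4 and 4 from 21 and 19 (4.6e-08, exact) and Mcc to 15 and 11 from 32 and 27 (8.91e-05, exact). Magi1, Thsd4, Eea1 and Lingo2 completed the falls, at exact adjusted p from 6.34e-06 to 0.000884. High-ranking gained regions lay inside Rabgap1l (chromosome 1, 160684431 to 160684446), Pcsk6 (chromosome 7, 65934419 to 65934750) and Mme. High-ranking lost ones lay inside Thsd4 (chromosome 9, 60351287 to 60351304) and Lingo2 (chromosome 4, 35861408 to 35861410).

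**Figure D2:**
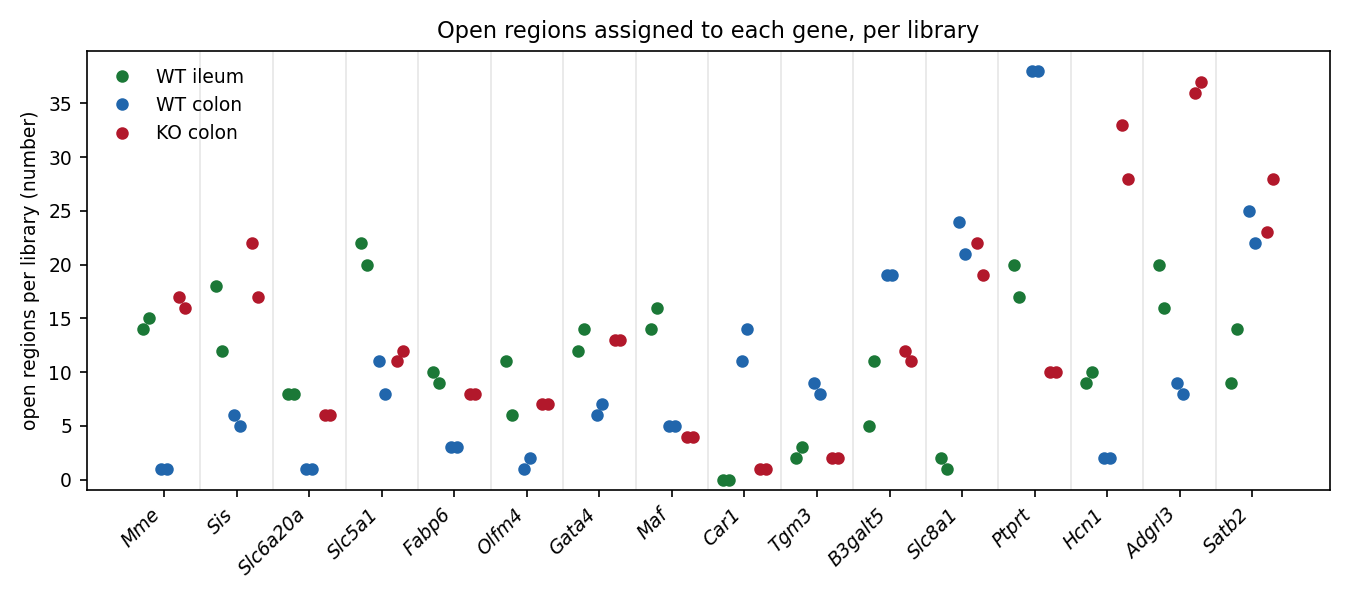
Number of regions per library at 16 of the named genes, chosen after their values were seen, with 1 point for each of the 2 libraries of a group. Mme has 14 and 15 regions in ileum, 1 and 1 in wild-type colon and 17 and 16 in knockout colon, while Hcn1 has 33 and 28 in knockout colon.

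**Figure D3:**
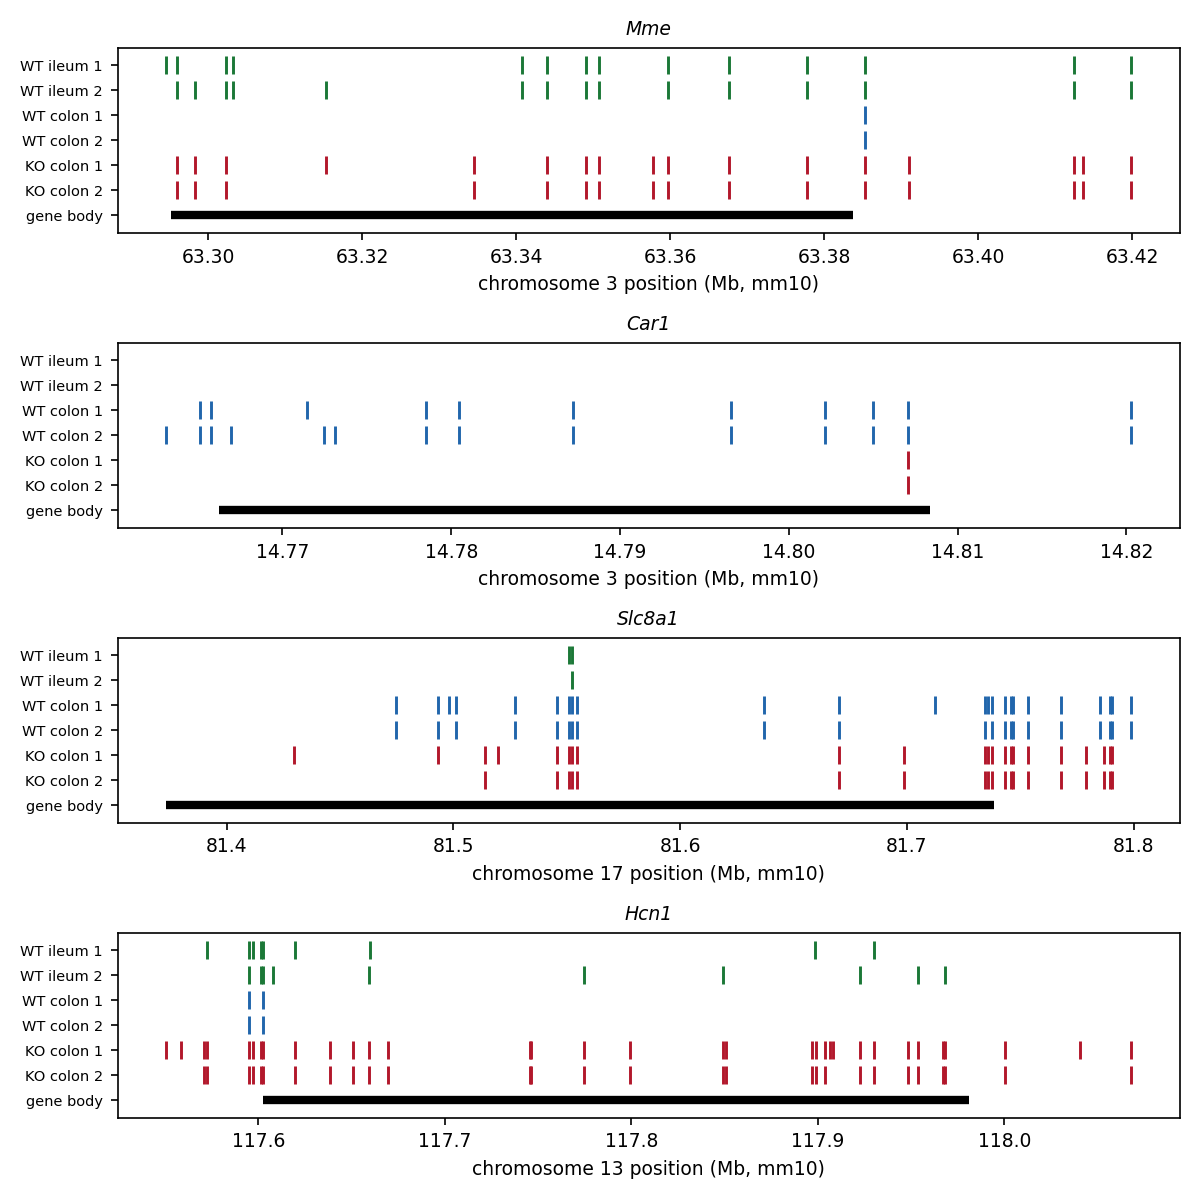
Regions of 4 genes along mm10 coordinates, with 1 track per library. Mme has 17 and 16 regions in knockout colon and Car1 1 and 1, Slc8a1 has 12 colon-only regions found in both knockout libraries and 6 found in neither, and Hcn1 has 15 regions found in knockout colon alone; these genes were chosen after their values were seen.

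In the main setting the brush-border list was the only one of 22 to pass, with 61 gained and 14 lost regions, a net of 1.88 per gene against −0.171 in random lists (permutation adjusted p 0.00352). Mme (15 gained, 0 lost) and Sis (8 and 0) gave the largest net gains, and the median over the list was 1. Of its members 14 leaned to gain, 2 to loss and 9 had a net of 0, and 4 of 24 tested were called with more regions, 5 adjusted over the list alone. They included Mme, Sis and Slc6a20a (6 and 6 against 1 and 1), whereas Slc5a1 had 11 and 12 against 11 and 8 and was not called. Xenobiotic metabolism had 36 gained and 16 lost regions (permutation adjusted p 0.0602), with Cyp3a25 (8 and 7 against 2 and 1) and the carboxylesterase gene Ces2a (14 and 13 against 6 and 7) called with more, 3 over the list alone. Colonic ion and water transport had 22 and 55 (permutation adjusted p 0.0602), with 3 genes called with fewer, 4 adjusted over the list alone, among them Car1 and the chloride exchanger gene Slc26a3 (9 and 10 against 15 and 15). The colonocyte list had 2 and 22 (permutation adjusted p 0.0602), with B3galt5 (12 and 11 against 19 and 19) and Tgm3 (2 and 2 against 9 and 8) called with fewer, 3 over the list alone. Lipid absorption had 27 and 10 (permutation adjusted p 0.0746), with Acsl5 called with more, 2 over the list alone. Of single genes, Fabp6, Olfm4, Gata4 and Klf5 were called with more regions, and the bile acid exporter gene Abcc3, Glis3, Cdkal1 and the neuronal gene Phox2b with fewer.

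Neuron and glia markers had 0 gained and 6 lost regions (permutation adjusted p 0.106). The remaining 16 lists had adjusted p from 0.413 to 0.939 by the same permutation test. Gained and lost regions were 11 and 10 for bile acid handling, 6 and 5 for Paneth cells, 17 and 10 for goblet cells, 6 and 11 for posterior Hox genes, and 60 and 43 for intestinal transcription factors. They were 27 and 38 for stem cells and Wnt, 8 and 7 for the cell cycle, 6 and 10 for enteroendocrine cells, 7 and 13 for tuft cells, 3 and 6 for MHC class II, and 7 and 4 for housekeeping genes. Markers of other cells had 2 and 3 for T cells, 0 and 1 for B cells, 2 and 5 for myeloid cells, 5 and 3 for stroma, and 7 and 5 for endothelium. Of 33 named gene calls 16 were kept whichever of the 4 libraries was left out, among them Mme, Sis, Car1, Hcn1, Adgrl3 and Ptprt. The calls for Abcc3, Acsl5, B3galt5, Ces2a, Cyp3a25, Fabp6, Fbxl17, Gata4, Klf5, Olfm4, Phox2b, Slc26a3 and Slc6a20a ended in each omission, with exact adjusted p up to 0.408, and the genes called numbered 71 and 120 without wild-type colon replicates 1 and 2, and 89 and 80 without knockout replicates 1 and 2.

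**Figure D4:**
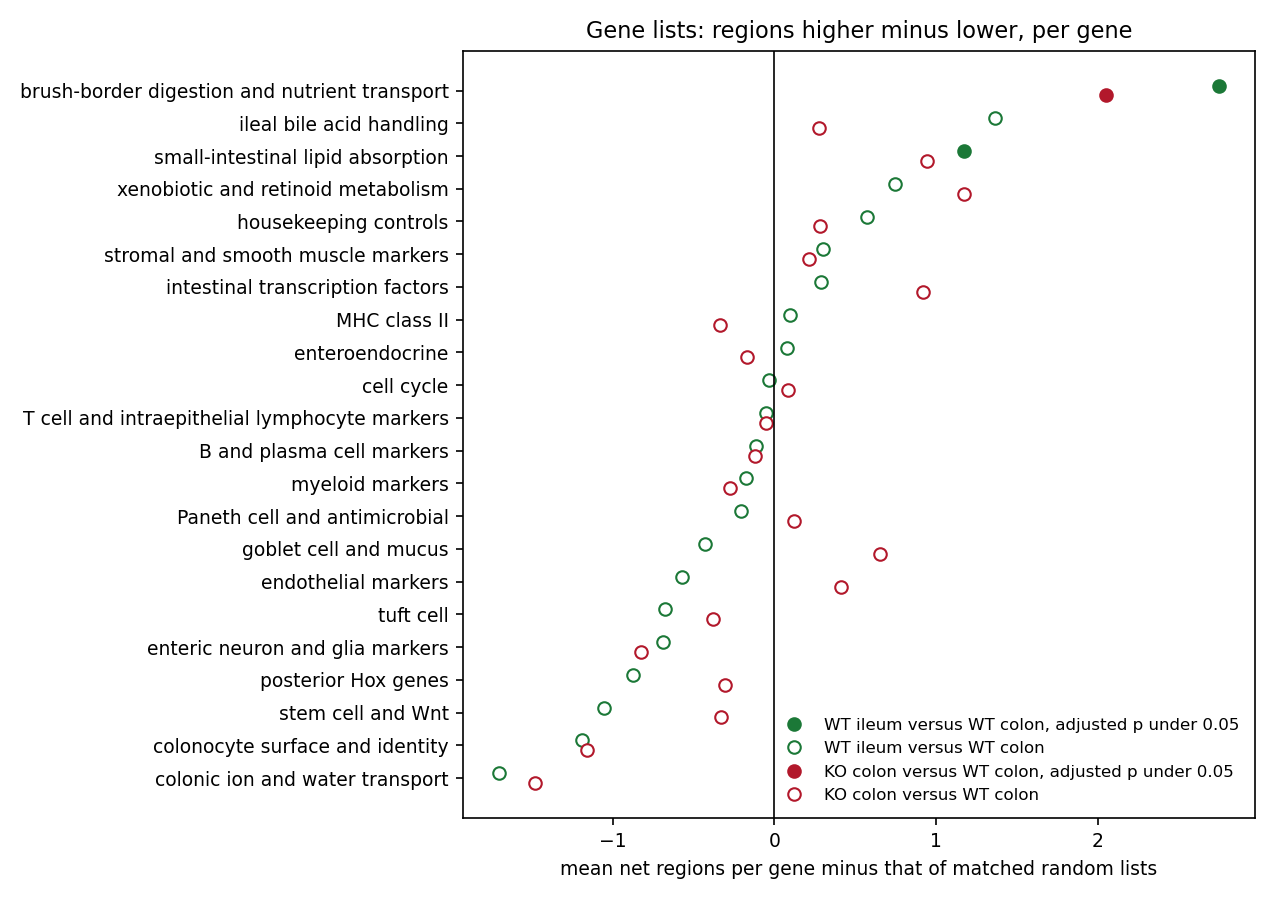
Mean net regions per gene of the 22 lists (ileum-only minus colon-only, or gained minus lost) less the mean of matched random lists, with filled points for a permutation adjusted p under the threshold. The brush-border list lies highest in both comparisons, at 2.75 and 2.05 regions per gene above random lists.

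Knockout colon libraries held a large part of the regions that mark the ileum. Of ileum-only regions defined without the held-out colon library, 55.5% ± 3.21 were found in a knockout library, against 13.3% ± 5.45 in the held-out wild-type colon library (SD, n = 2). Of colon-only regions, 21.4% ± 2.88 were found in knockout and 80.5% and 69.5% in held-out wild-type colon (SD 7.84, n = 2). The differences, 42.2 and −53.6 percentage points, exceeded the replicate SDs, and both had an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. Without ileum replicate 1 the ileum-only difference was 27.5 points. The share of ileum-only regions found in both knockout libraries was 44.9% of all and 84.1% of the 637 in the top 25% of both ileum lists. Of the gained regions, 47.6% were found in both ileum libraries and 27.9% in neither, and of the lost regions 78.0% were found in neither ileum library and 7.03% in both.

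**Figure D5:**
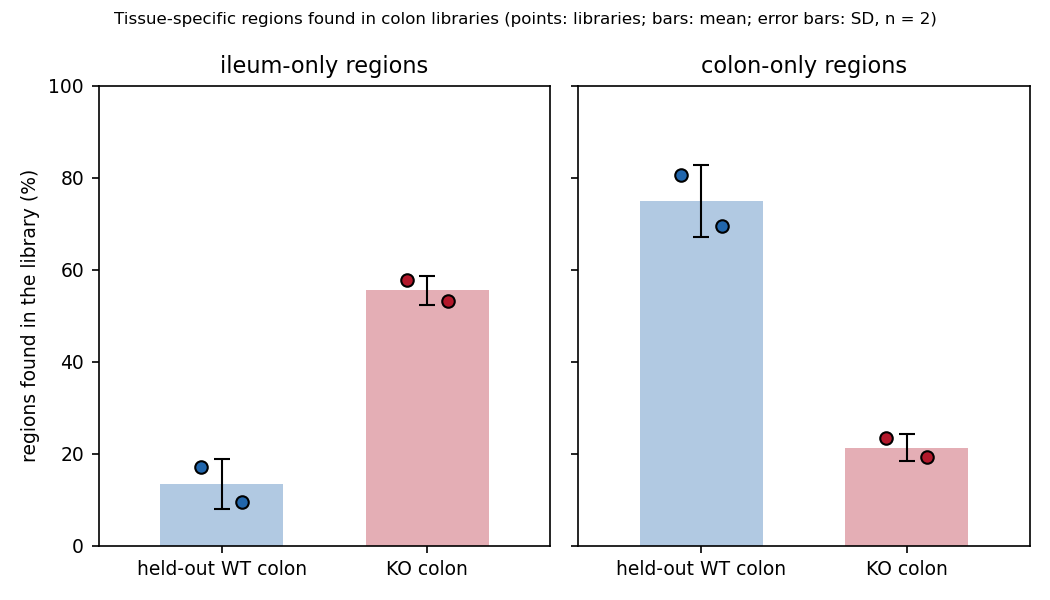
Percent of ileum-only and colon-only regions found in knockout colon libraries and in the held-out wild-type colon library, with points for libraries, bars for means and error bars for the SD (n = 2). Ileum-only regions are found at 55.5% in knockout against 13.3%, colon-only regions at 21.4% against 69.5% and 80.5%.

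The same genes were called in both comparisons more often than independent lists would give. Mme, Sis, Fabp6, Olfm4 and Gata4 were among 61 genes with more regions in both ileum and knockout colon than in wild-type colon, against 2.77 for independent lists. Car1, Ptprt, Lrmda, Ldlrad3 and Tgm3 were among 139 with fewer in both, against 6.90, and none was called in opposite directions. Of the 241 genes with more regions in ileum 95.0% also leaned to more in knockout, and of the 309 with fewer 95.2% leaned to fewer. Unchanged groups simulated against the same controls leaned the same way at 63.9% and 70.6% of these genes. They had a mean of 0.05 genes called with more regions and 0 with fewer, so they give no reference for the number of genes called in both. Among regions, 5602 were ileum-only and gained, against 1205 for independent lists, and 10403 were colon-only and lost, against 1660. Simulated unchanged groups gained a mean of 1665 regions, of which 20.1% were ileum-only against 47.6% of the observed gains. They lost a mean of 1664, of which 60.6% were colon-only against 78.0% of the observed losses. The overlaps were not repeated with split controls, since each part would hold 1 library, so part of these excesses may come from the shared controls. For regions, the shares in knockout against the held-out wild-type colon library, 55.5% against 13.3% for ileum-only regions, are free of the library used to define them.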

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

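The gene body assignment, the exact permutation test per gene and its replicate block were chosen after the data were seen, and all other alternatives were planned. Of 130 alternative values of the 10 main results, 85 stayed within the limits set and 45 moved, and the differences in ileum-only and colon-only regions kept their sign. With the top 33214 summits of each list there were 6482 ileum-only, 7719 colon-only, 6568 gained and 6429 lost regions, fewer by construction. The difference in ileum-only regions was 49.7 percentage points there, 135 genes differed between ileum and colon and 73 between knockout and wild-type colon, and 5 lists passed for knockout. The planned limma fit called 1508 and 1123 genes, and the balance of calls moved with it: 857 with more and 651 with fewer regions in ileum, against 241 and 309 by the exact test, and 555 and 568 for knockout, against 126 and 245. With a pseudocount of 0.5 it called 1494 (862 more, 632 fewer) and 1162 (581 and 581). Fisher's exact test per gene called 0 of 9428 and 4 of 8969 (3 more, 1 fewer). With gene bodies and 10 kb around them 288 and 189 genes differed and 2 lists passed for knockout. Joining within 100 bp gave 239 genes for knockout. Within 25 kb, 229 genes differed for knockout and 4 lists passed in each comparison. Lists of equal length gave 3 lists for knockout. The balance for knockout was more even there, with 12366 gained and 12388 lost regions, and 151 genes with more and 198 with fewer. Except where fewer regions or samples entered, the cause was not tested.

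Leaving out 1 library at a time, those of the third group included, gave 12485 to 24785 ileum-only regions and 13353 to 20388 lost regions. The ileum-only difference ranged from 27.5 to 44.4 percentage points and the colon-only difference from −55.7 to −41.7. These differences have no value without a wild-type colon library, since 1 library must be held out. Genes called ranged from 122 to 551 between ileum and colon and from 71 to 378 for knockout, and lists passing from 1 to 5 in both comparisons. Fewer libraries leave fewer permutations, and 8 of 45 named calls between ileum and colon and 13 of 33 for knockout were kept in none of the 4 omissions.

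In the region numbers of genes, replicate numbers did not pair the libraries: the correlations of same-numbered differences between groups were −0.0183, 0.0294 and 0.0196. Single regions left some pairing possible. Splits with same-numbered libraries together separated 1978 regions for ileum against wild-type colon, 1414 for knockout against wild-type colon and 2715 for ileum against knockout. Crossed splits separated 1721, 1120 and 2225. With a replicate block the exact test called 272 and 161 genes, limma 1159 (641 more, 518 fewer) and 847 (420 and 427), and the paired differences were 42.2 and −53.6 percentage points. The planned motif alternatives (a window of 50 bp, matching for GC content, and regions over 1 kb from genes) were not run for lack of a genome sequence. The unknown sequencing depth limits all statements of absence to the called lists.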

Other observations

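The direct comparison of ileum with knockout colon, the region classes and 6 of the 9 tests of explanations (those on labels, list length, the variance of ileum-only regions, the calling threshold and neuron markers) were chosen only after the results were seen, as was the margin asked of the tests of variance. The test of long genes is not counted among these 6, but it was built on 5 genes chosen after their values were seen. Set against each other, wild-type ileum and knockout colon differed at fewer genes than either did from wild-type colon. The exact permutation test called 54 genes with more regions in ileum and 56 with more in knockout colon, of 10976. Slc8a1, the sodium-calcium exchanger gene, had 22 and 19 regions in knockout colon against 2 and 1 in ileum (exact adjusted p 8.11e-11). Against wild-type colon, 4 of its regions were gained and 6 lost. The transcription factor gene Maf had 4 regions in each knockout library against 14 and 16 in ileum (exact adjusted p 0.000354). Auts2, with 77 and 70 regions in knockout colon against 54 and 39, differed likewise (exact adjusted p 2.43e-07). Pdzrn3, chosen after its values were seen, had 23 and 16 regions in knockout colon against 6 and 5 in ileum (exact adjusted p 1.01e-05). None of the 22 lists passed this comparison by the permutation test (smallest adjusted p 0.470). The brush-border list, with 29 regions in ileum alone against 13 in knockout colon alone, was the 1 list with an unadjusted p under 0.05.

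Regions also sorted by which of the 6 libraries held them. Both ileum and both knockout libraries, but neither wild-type colon library, shared 5602 regions, of which Mme held 10. Both wild-type colon and both knockout libraries, but neither ileum library, shared 2721, of which Slc8a1 held 12 and Mecom 7. Knockout colon alone held 3279, ileum alone 5016 and wild-type colon alone 10403. All 4 wild-type libraries but neither knockout library held 938 regions. Pde10a, a phosphodiesterase gene chosen after its values were seen, had 7 of these, and had 11 and 11 regions in the ileum libraries, 11 and 12 in wild-type colon and 2 and 1 in knockout colon (exact adjusted p 2.18e-05 for knockout against wild-type colon). Satb2 had 1 of them, at chromosome 1, 56916061 to 56916106, also chosen after it was seen. The ileum libraries shared 60.9% of their joint regions, while ileum replicate 1 shared 62.9% and 62.6% with the knockout libraries.

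Knockout colon libraries held ileum-only regions and lacked colon-only regions. A wrong label on wild-type ileum would make the libraries alike, provided that ileum libraries are alike among themselves. Yet 13232 regions separated ileum from knockout against 2715 in the larger other split. The ileum libraries shared only 60.9% of their joint regions, so this count cannot exclude wild-type ileum of another preparation. With equal list lengths the ileum-only difference was still 45.5 percentage points, with a replicate SD of at most 1.26. Ileum cells mixed into the knockout samples would bring the strongest ileal regions first. The share of colon-only regions kept in knockout also rose with strength, from 18.0% to 42.4%, so such a rise cannot single out mixing. The share of ileum-only regions found in both knockout libraries rose from 44.9% of all to 68.9% of the 3313 above the median of both ileum lists and 84.1% of the 637 in their top 25%. Over 353 genes, the variance between genes of that share was 1.33 times that in shuffles among regions of like strength (highest shuffle 1.22), about the 1.32 and 1.19 of ileum libraries held out, while a test fixed in advance went against mixing, with 1.51% of 31811 strong knockout regions in no wild-type list against 1.09% and 1.21% missing between the wild-type colon lists, but it allowed for no regions of the knockout cells' own, which would give this excess with or without ileum cells. Opening of ileal regions in colon cells without Satb2 and admixed ileum cells therefore cannot be told apart here. Knockout ileum under a colon label, strain background and a difference in depth or quality of the wild-type colon libraries stay untested.

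Some colon-only regions stayed in both knockout libraries, 18.0% of 15132. The share rose with strength, to 31.6% of the 3346 above the median of both wild-type colon lists and 42.4% of the 625 in their top 25%, so weak regions were not kept more often than strong ones, and a remainder of unchanged colon cells would give such a rise too. A remainder that sampled all colon cells evenly would let strength alone decide. Yet over 531 genes the variance between genes of the share kept was 1.37 times that in shuffles among regions of like strength. The highest of 1000 shuffles gave 1.21, and wild-type colon held out gave 1.13 and 1.19. The held-out values counted regions of a single library found in the other, not regions found in both libraries, so they are not a like measure. In ileum libraries held out in the same way, which differ only as replicates, that ratio reached 1.32. An excess over the shuffles alone therefore cannot decide whether an even remainder was the whole account. Such a remainder may add a part, and a remainder of particular colon cells was not tested. Some colon regions may not need Satb2, with Slc8a1, where 12 of 19 colon-only regions stayed, a candidate locus.

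Regions found in knockout colon alone were most numerous at Hcn1 (15 regions), Adgrl3 (10), Rabgap1l (9) and Grik1 (8), then at Macrod2, Auts2 and Nrxn3 (7 each) and Kcnip4, Cadm1 and Dock4 (6 each), while Macrod2 and Auts2 also had 15 and 14 found in wild-type colon alone. The first 4 genes and Neto1 (4 regions), all from the 8 largest rises and chosen after their values were seen, were tested further, although Hcn1 (9 and 10 against 2 and 2), Adgrl3 (20 and 16 against 9 and 8) and Neto1 (7 and 4 against 1 and 1) also had more regions in ileum than in wild-type colon by the exact test (adjusted p 0.00302, 0.0149 and 0.0396). With the top 33214 summits of each list, 4 of these 5 still rose by the exact test, Rabgap1l being the exception (exact adjusted p 0.163), so their rises did not rest on summits near the threshold alone. The fixed neuron and glia markers had a net of −0.857 regions per gene, 0 gained and 6 lost, and the sort selected epithelium. These 7 genes had 22 regions in all, and the losses lay at Phox2b (4) and Sox10 (2). So few regions cannot exclude a greater share of such cells, though none was seen. The median net gain was 0 among 1725 other genes at least as long as the shortest of the 5. Of these genes 9 in 10 gained at most 3, and the highest gain was 11, so long genes did not gain regions in general. Net gain, like the exact test, also counts gained regions found in ileum. Of regions found in knockout colon alone, the 1725 genes had a median of 0 and 9 in 10 had at most 2, against 4 to 15 at the 5. The 5, with a net gain of 10 or more each, were chosen for their rise, and strain background stays untested.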
